A study of Homo sapiens with 6 samples.

How the data were processed

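The data were RNA sequencing counts of 6 libraries of T24 bladder cancer cells, 3 from cells with a control lentivirus and 3 from cells with a short hairpin RNA against MTHFD2. Per the labels' protocols, infected cells were selected with puromycin, RNA was extracted with Trizol, and Illumina libraries were made from RNA of high integrity. The series' design text speaks of a knockout, while the treatment protocol and the titles name a hairpin, so the text here calls it a knockdown. The series used more than 1 hairpin, and the libraries analysed here carry the one its titles number 2. Per the submitters' processing notes, HISAT2 version 2.0.4 and the genome build GRCh38 were used. The counting tool, the gene annotation, the library's strandedness and any read filter are not given in the sources used here. The authors deposited whole-number counts per gene, not normalized, in a single table of 54261 gene symbols, of which 25308 had at least 1 count. No row of that table lacked a gene name, and every column was used.

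Library totals ran from 17801990 to 19978392 counts. A count of 3, the most that a count of 0 in a library allows, equals 0.15 to 0.169 CPM at these depths, so genes below about that level could not be measured. Such floors, and the intervals given for ratios of counts, cover counting error only, since reads without molecular identifiers are not independent molecules. Reads from genes that overlap on opposite strands, and from near-identical copies such as metallothionein genes or keratin pseudogenes, could have been assigned to either copy.

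Groups were taken from the titles. No pair of libraries in a group agreed within sampling noise: chi-square per degree of freedom lay between 2.61 (control replicates 1 and 2) and 34.1 (knockdown replicates 2 and 3), so each library counted as 1 sample. On log2 CPM the first principal component held 56.5% of the variance and separated the groups, and the second held 19%.

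Genes were kept by edgeR's filterByExpr, scaled by TMM and tested with edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest, robust; edgeR 4.0.16, limma 3.58.1, R 4.3.3), knockdown against control, with Benjamini-Hochberg adjustment over 13896 genes and a threshold of 0.05. A standard error of a log2 fold change is its size divided by the square root of F. CPM values are on TMM-scaled library sizes, and log2 CPM used a prior count of 2. Coordinates, exonic length and GC content came from GENCODE release 29 on GRCh38, matched by symbol, for 35375 symbols.

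The design, the alternatives and the lists were fixed before the data were examined. There were 33 gene lists: folate metabolism, serine synthesis, purine and pyrimidine synthesis, ATF4 targets, endoplasmic reticulum chaperones, the PI3K, AKT and mTOR core, receptors and matrix upstream of PI3K, FOXO targets, checkpoint ligands, interferon receptors with JAK and STAT factors, interferon-stimulated genes, antigen presentation, NF-kB cytokines, ERK output, G1/S, G2/M, p53 targets, apoptosis, mesenchymal genes, epithelial genes, YAP targets, cholesterol synthesis, fatty acid synthesis, glycolysis and hypoxia, nuclear respiratory chain, mitochondrial genome, NRF2 and glutathione, ribosomal proteins, ribosome biogenesis, histones, immediate early genes and RNA sensing. MTHFD2 is in none of them. In addition, 5 lists held markers of leukocytes, fibroblasts, endothelium, hepatocytes and embryonic kidney or neural cells. A single listed symbol, a histone, had no match in the table. Lists with at least 5 tested members were tested with camera on log2 CPM with a preset correlation of 0.01, which compares a list with the other genes, and beside it with an estimated correlation and with fry. The alternatives were RLE scaling, DESeq2 1.42.0, other low-count filters, the replicate number as a block, each library left out, a stricter threshold of 0.01 and, for lists, voom weights.

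Genes named in the text are MTHFD2 and CD274, then the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 2 log2 CPM, no overlap between the groups and a symbol that is not a clone name. From each list up to 4 members past the threshold were named by size, with each direction present where there was one, and where none passed, up to 2 of the most abundant members. Other genes are named only where the text says so or as markers of other cells.

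The procedures were tested on simulated data first. For knockdown against control, counts were drawn for the 13896 tested genes with known folds in 200 genes. The edgeR test recovered 46% of genes changed 1.5-fold, 80% at 2-fold, 98% at 3-fold and 96% at 4-fold, and 3.5% of its calls were false. DESeq2 recovered 46%, 76%, 98% and 96%, with 7.7% false calls. Of 20 unchanged simulated lists camera called 0, and it called the 1 list lowered 1.4-fold. The simulated genes were drawn independently of one another, so this check does not cover lists whose members are correlated. In the data the estimated correlation was 0.193 for NF-kB cytokines and 0.398 for ribosome biogenesis. The correction for GC content and length, per-library loess trends used as offsets, took a planted trend from a rank correlation of -0.76 to -0.01.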

Results

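Gene expression was measured by RNA sequencing in 6 libraries of T24 cells, an established human bladder cancer line. In 3 libraries the cells carried a control lentivirus, and in 3 they carried a lentivirus with a short hairpin RNA against MTHFD2, an enzyme of folate metabolism in mitochondria. The control libraries held 17801990, 19435833 and 19978392 counts and the knockdown libraries 19896302, 18769214 and 18452506. The labels number the replicates 1 to 3 in each group and do not say whether these were separate cultures, so the p-values measure the spread between these samples, which may be technical.

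The series asks how loss of MTHFD2 bears on PD-L1, the product of CD274, and on PI3K and AKT signalling. The target itself fell in every knockdown library. MTHFD2 (GRCh38 chromosome 2, 74198562 to 74217565, plus strand) was at 185 ± 3.18 CPM in the control libraries and 32.4 ± 5.12 CPM in the knockdown libraries (SD, n = 3 each). Its log2 fold change was -2.51 ± 0.13 (SE; edgeR adjusted p = 1.8e-06). The single libraries held 3241, 3613 and 3417 MTHFD2 counts in the control group against 538, 667 and 686 after knockdown.

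With MTHFD2 lowered, the inflammatory cytokine IL6 fell furthest among well expressed genes. It went from 12.7 ± 1.29 to 1.68 ± 0.438 CPM, a log2 fold change of -2.91 ± 0.20, and the neutrophil-attracting chemokines CXCL1 and CXCL8 fell by 2.29 and 1.97 on the log2 scale. Genes of ribosome assembly and of cholesterol synthesis also fell as groups by camera with its preset correlation, a call that both lost with an estimated correlation (adjusted p = 0.511). Among the genes that rose were JUP, which encodes the junction protein plakoglobin, and BMF, a member of the BCL2 family that promotes cell death. CD274 rose as well, from a very low level.

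Of 13896 genes tested, 2402 changed at an edgeR adjusted p under 0.05, or 17.3%. The knockdown libraries were higher for 1349 of them and lower for 1053. A change of at least 2-fold was reached by 515 genes, 392 higher and 123 lower. The 3 knockdown libraries lay wholly above or below the 3 controls for 39.1% of tested genes, where chance alone gives 10%. The count of changed genes was 1003 without control replicate 1, 986 without control replicate 3 and 1469 without knockdown replicate 2. With knockdown replicate 2 alone against the controls, 4432 genes passed, on the assumption that a lone library varies like the others.

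The largest rises among well expressed genes were in KIF12, a kinesin (2.22 ± 0.26 on the log2 scale, SE), BLACAT1, a long noncoding RNA named for bladder cancer (2.18 ± 0.21), and TUBB4A, a beta tubulin (2.04 ± 0.18). BMF, GPR155, the cyclic GMP phosphodiesterase gene PDE5A, NOL4L, the secretory granule gene SCG2, CSGALNACT1 and the collagen gene COL1A1 followed, between 1.99 and 1.83. After IL6 and MTHFD2, the largest falls were in IGFN1 (-2.36 ± 0.24) and CCBE1 (-2.30 ± 0.23). CXCL1, CXCL8, the BMP antagonist NOG, the chemokine CCL20, the metallothionein MT1E and complement C3 followed, down to -1.67. All 20 of these genes passed the edgeR test, with adjusted p-values up to 0.0077 for COL1A1. The rise of COL1A1 lay in knockdown replicates 1 and 3, which held fibroblast markers: with knockdown replicate 2 alone its log2 fold change was 0.47. Without control replicate 2 the call of COL1A1 was lost (edgeR adjusted p = 0.0738), but its log2 fold change stayed at 1.855 ± 0.544, with a larger standard error. Metallothionein genes are near-identical in sequence, so reads of MT1E may be shared with its relatives.

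**Figure D1:**
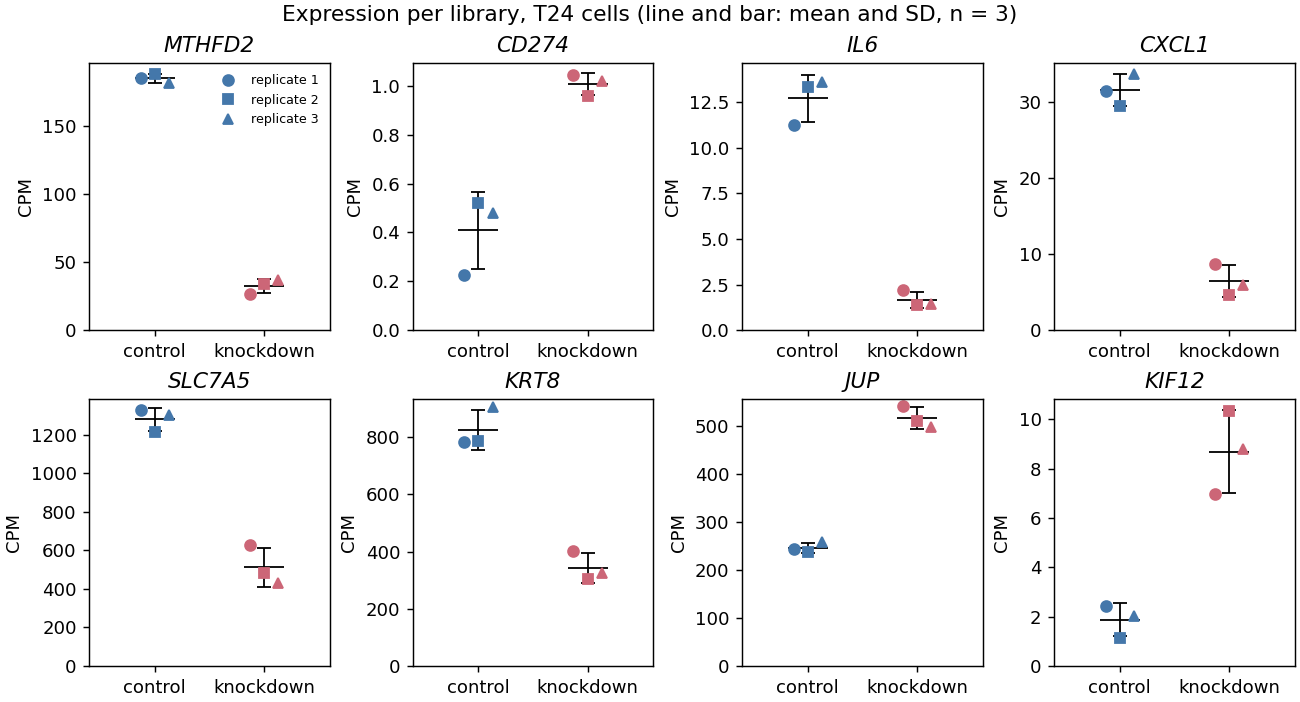
CPM of 8 named genes in each library, one panel per gene, for the 3 control and 3 knockdown libraries. Points are libraries, and the line and bar give the mean and SD. MTHFD2 lies near 185 CPM in the control libraries and near 32.4 CPM after knockdown, while CD274 stays close to 1 CPM or below.

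CD274 (chromosome 9, 5450503 to 5470566, plus strand) was higher in all 3 knockdown libraries. It held 4, 10 and 9 counts in the control libraries and 21, 19 and 19 after knockdown, or 0.409 ± 0.158 against 1.01 ± 0.0442 CPM (SD, n = 3). The log2 fold change was 1.27 ± 0.39 (SE; edgeR adjusted p = 0.042). The call rests on these few counts: the adjusted p was 0.127 by DESeq2 and 0.0569 in edgeR without the low-count filter. It lay between 0.0686 and 0.176 when any single library, control or knockdown, was left out, with a log2 fold change between 1.00 and 1.47.

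Other immune checkpoint ligands and PD-L1 stabilisers went both ways. Of 17 tested members of that list, CD274 included, 3 rose and 3 fell, and the count adjusted over the list alone was also 6. CMTM4, which stabilises PD-L1 protein, rose by 0.72 ± 0.16 on the log2 scale, while PVR (-0.55 ± 0.11) and TNFSF9 (-0.47 ± 0.13) fell. The list did not move as a whole (camera adjusted p = 0.609).

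Genes of PI3K, AKT and mTOR signalling also changed in both directions. Of 37 core components tested, 4 rose and 4 fell, with 8 adjusted over the list alone. The adaptor PIK3AP1 (1.07 ± 0.21) and the class II kinase PIK3C2B (0.97 ± 0.16) rose. The proapoptotic AKT substrate BAD (-0.54 ± 0.15) and the mTORC1 subunit AKT1S1 (-0.54 ± 0.13) fell. The median over the list was 0.02 (camera adjusted p = 0.871). Of 55 receptors, ligands, integrins and matrix genes placed upstream of PI3K, 12 rose and 11 fell, with 30 adjusted over the list alone. FGF1 fell by 2.68 ± 0.46, from 22, 34 and 31 counts in the control libraries to 9, 2 and 3 after knockdown, near the floor of 3 counts. FGFR3 rose by 1.34 ± 0.39, a call that edgeR lost in 5 of the 6 fits leaving out a library. COL1A2 and COL1A1, matrix ligands of integrins, rose by 2.22 ± 0.55 and 1.83 ± 0.37, but in knockdown replicates 1 and 3, which also held fibroblast markers. With knockdown replicate 2 alone their log2 fold changes were 0.04 and 0.47. COL1A2 lost its call without the low-count filter (edgeR adjusted p = 0.246) and in 4 of the 6 fits leaving out a library. Its log2 fold change stayed at 2.22 without the filter and between 2.15 and 2.29 without a control library, with larger standard errors. It was 1.74 without knockdown replicate 1. The upstream list did not move as a whole (camera adjusted p = 0.678).

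Transcripts that FOXO factors raise, and that AKT restrains through FOXO, had a median of 0.33. Of 21 tested, 7 rose and 4 fell, with 13 adjusted over the list alone. PIK3IP1, an inhibitor of PI3K (1.34 ± 0.25), KLHL24 (0.99 ± 0.19) and BCL6 (0.94 ± 0.26) rose, and GADD45A fell by 1.23 ± 0.15. The list did not pass with all libraries (camera adjusted p = 0.0879; 0.59 with an estimated correlation). It passed without control replicate 1, control replicate 2 or knockdown replicate 1 (camera adjusted p = 0.0358, 0.0332 and 0.0229), without the low-count filter (camera adjusted p = 0.0391) and with knockdown replicate 2 alone (camera adjusted p = 0.0481), so its call depends on the setting.

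NF-kB targets and cytokines formed the list with the lowest p. Of 27 tested, 19 fell and 1 rose, with 21 adjusted over the list alone, and the median was -0.59 (camera adjusted p = 1.15e-09). With an estimated correlation between members the list gave an adjusted p = 0.511. IL6, CXCL2 (-2.35 ± 0.30) and CXCL1 (-2.29 ± 0.19) fell most. TNFAIP6, a secreted protein that binds hyaluronan, rose by 1.37 ± 0.25.

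Of 33 genes of ribosome biogenesis that MYC drives, 19 fell and none rose, with 23 adjusted over the list alone. Their median was -0.50 (camera adjusted p = 8.19e-09; adjusted p = 0.511 with an estimated correlation). The spermidine synthase gene SRM fell by 0.88 ± 0.14, from 138 ± 21.8 to 74.9 ± 12.2 CPM. LYAR, RRP12 and RRS1, which act in assembly of the ribosomal subunits, were lower by -0.86 ± 0.15, -0.80 ± 0.15 and -0.75 ± 0.13. Of 52 ribosomal protein genes tested, 1 fell and none passed when adjusted over the list alone (camera adjusted p = 0.0879). That list hangs on single libraries: its median of -0.10 became -0.23 without knockdown replicate 3 (camera adjusted p = 0.000137) and -0.41 with knockdown replicate 2 alone (camera adjusted p = 1.66e-06), and it also passed without control replicate 1 or 2 (camera adjusted p = 0.0233 and 0.0118). With an estimated correlation, which was 0.919 between its members, it was far from passing (camera adjusted p = 0.856), so the p-values at the preset 0.01 carry little weight here. The gene that fell, RPL9 (-0.42 ± 0.13), has many processed pseudogenes that could take part of its reads, and edgeR lost its call in 5 of the 6 fits leaving out a library.

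Cholesterol synthesis genes fell in 11 of 23 cases and rose in none, with 13 adjusted over the list alone. The median was -0.37 (camera adjusted p = 5.32e-05; adjusted p = 0.511 with an estimated correlation). MVK, DHCR7 and MVD fell by 0.71 ± 0.17, 0.62 ± 0.14 and 0.57 ± 0.15. In fatty acid synthesis, 3 of 17 genes fell and 1 rose, with 6 adjusted over the list alone (camera adjusted p = 0.091; 0.59 with an estimated correlation). That list passed without the low-count filter (camera adjusted p = 0.0453) and without GC content and length trends (camera adjusted p = 0.00936). ACLY, which makes cytosolic acetyl-CoA, FADS2 and ELOVL1 fell by 0.78 ± 0.14, 0.50 ± 0.12 and 0.42 ± 0.11. The acetyl-CoA carboxylase ACACB rose by 1.05 ± 0.21.

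ATF4 and amino acid response genes fell in 10 of 33 cases and rose in 3, with 14 adjusted over the list alone. The median was -0.16 (camera adjusted p = 0.00436; adjusted p = 0.511 with an estimated correlation). SLC7A5, the light chain of the leucine transporter, went from 1280 ± 60.5 to 513 ± 101 CPM, and the transcription factors ATF5 (-1.20 ± 0.20) and CEBPB (-1.12 ± 0.15) fell too. VLDLR, a lipoprotein receptor, rose by 1.15 ± 0.21.

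Enzymes of folate metabolism other than the target did not move as a list (camera adjusted p = 0.321). Of 25 tested, 2 rose and 4 fell, with 6 adjusted over the list alone. SHMT2, which supplies one-carbon units in mitochondria, fell by 0.42 ± 0.11, and the folate carrier SLC19A1 by 0.58 ± 0.13. ALDH1L2, a mitochondrial formyltetrahydrofolate dehydrogenase, rose by 2.15 ± 0.52, from 0.256 ± 0.148 to 1.14 ± 0.542 CPM. It held 7, 2 and 5 counts in the control libraries and 16, 35 and 16 after knockdown. Its call was lost without control replicate 2 or 3 or knockdown replicate 2 (edgeR adjusted p = 0.0514, 0.0587 and 0.0658). The median of the list was -0.10 and its mean 0.02.

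Serine synthesis and transport genes numbered 8 tested, of which 3 fell and 1 rose, with 5 adjusted over the list alone (camera adjusted p = 0.767). PSAT1 (-0.54 ± 0.11) and the neutral amino acid transporter SLC1A5 (-0.54 ± 0.10) fell, while the racemase SRR rose by 0.41 ± 0.12, a call edgeR lost in 4 of the 6 fits leaving out a library. SLC1A4 fell too (-0.41 ± 0.13), a call lost by DESeq2 (adjusted p = 0.0648) and by edgeR in 5 of the 6 fits leaving out a library. Of this list the median was 0.06 and the mean -0.03, and the test pointed down. In purine synthesis, 1 of 15 genes passed, with 1 adjusted over the list alone: PRPS2 rose by 0.38 ± 0.10 (camera adjusted p = 0.699). The call of PRPS2 was lost without control replicate 1, 2 or 3 (edgeR adjusted p = 0.0979, 0.0773 and 0.0918). In pyrimidine synthesis, TK1, CTPS1 and DCTD fell by 0.41 ± 0.13, 0.41 ± 0.11 and 0.33 ± 0.10 among 15 tested, with 4 adjusted over the list alone (camera adjusted p = 0.0514; 0.511 with an estimated correlation). The list passed by fry (adjusted p = 0.0399), with voom weights (camera adjusted p = 0.03) and without GC content and length trends (camera adjusted p = 0.0189). Without GC content and length trends TK1 was at -0.18 and lost its call (edgeR adjusted p = 0.0936), and edgeR lost each of the 3 calls in 4 of the 6 fits leaving out a library.

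Cell cycle genes of G1/S and DNA replication fell in 8 of 44 cases and rose in none, with 10 adjusted over the list alone. Their median was -0.16 (camera adjusted p = 0.00114; adjusted p = 0.511 with an estimated correlation). CDT1, a licensing factor (-0.52 ± 0.12), the phosphatase CDC25A (-0.43 ± 0.12), TIPIN (-0.40 ± 0.12) and the helicase subunit MCM7 (-0.40 ± 0.11) fell. The calls of CDC25A, TIPIN and MCM7 were each lost in 4 of the 6 edgeR fits leaving out a library. Among 51 genes of G2/M, CDC20, PLK1 and FOXM1 fell by 0.49 ± 0.12, 0.42 ± 0.12 and 0.39 ± 0.10, and SPC24 rose by 0.42 ± 0.13. The call of PLK1 was lost in 5 and that of SPC24 in 4 of the 6 edgeR fits leaving out a library. None of the 51 passed when adjusted over the list alone, and in the main fit the list did not move (camera adjusted p = 0.219; 0.511 with an estimated correlation). It passed without GC content and length trends (camera adjusted p = 0.0213), where 7 members fell and 2 rose.

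**Figure D2:**
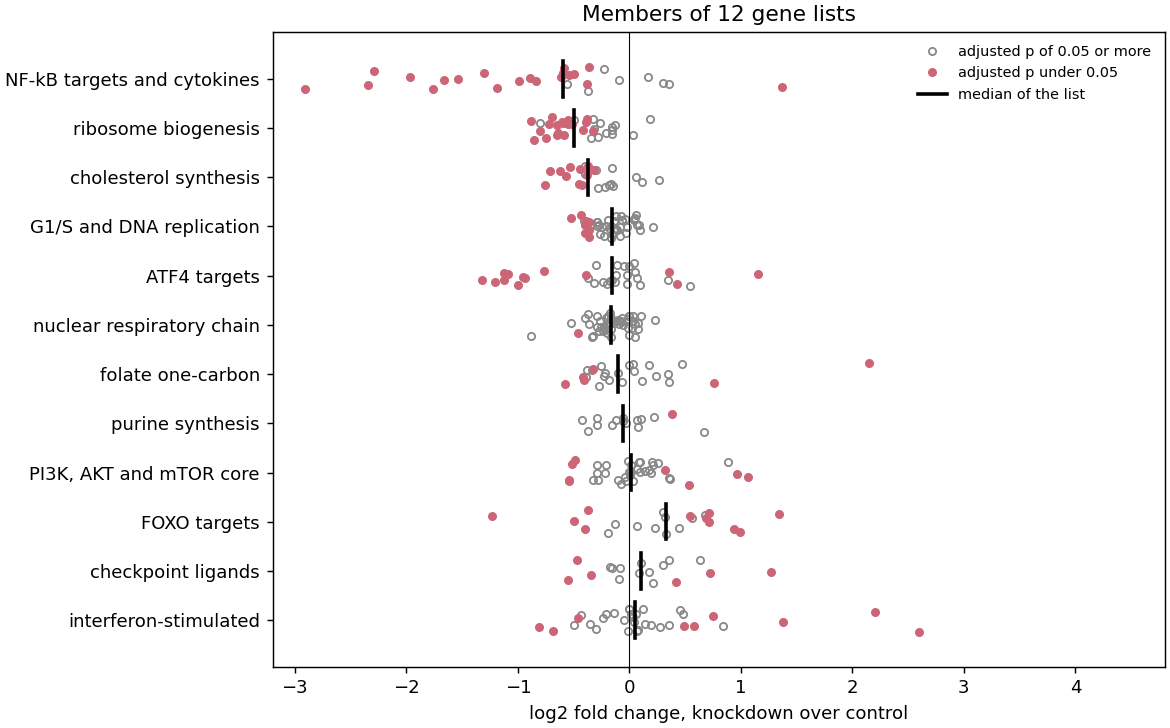
Log2 fold change, knockdown over control, of the tested members of 12 gene lists. Each point is a gene, filled where the edgeR adjusted p was under 0.05, and the bar is the median of the list. The NF-kB list sits furthest to the left, with a median of -0.59, and the PI3K, AKT and mTOR core list is centred at 0.02.

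Nuclear genes of the respiratory chain passed the list test with little change per gene. Of 53 tested, 1 fell and none rose, with 0 adjusted over the list alone (camera adjusted p = 0.0249; adjusted p = 0.789 with an estimated correlation). The gene that fell was COX8A (-0.46 ± 0.15), and edgeR lost its call in 5 of the 6 fits leaving out a library. The median was -0.16 and became -0.07 once trends on GC content and gene length were removed, a correction that ended the call of the list (camera adjusted p = 0.107) and of COX8A. The list also lost its call without control replicate 3 (median -0.06, camera adjusted p = 0.188), knockdown replicate 1 (-0.17, camera adjusted p = 0.0648) or knockdown replicate 2 (-0.04, camera adjusted p = 0.495). None of the 13 genes of the mitochondrial genome changed, alone or over all genes (camera adjusted p = 0.315). COX1 was at 7291 ± 219 CPM in the control and 7290 ± 432 CPM in the knockdown libraries, and COX2 at 4482 ± 280 and 4539 ± 732 CPM.

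Epithelial genes went both ways. Of 19 tested, 6 rose and 3 fell, with 11 adjusted over the list alone (camera adjusted p = 0.425; 0.59 with an estimated correlation). The list passed upward by fry (adjusted p = 0.0138). JUP rose from 246 ± 10.5 to 517 ± 22.7 CPM and the tight junction gene CLDN4 by 1.01 ± 0.24 on the log2 scale. The uroplakin UPK1A rose by 1.72 ± 0.40, from 0.412 to 1.38 CPM. The keratin gene KRT8, which has many pseudogenes, fell from 825 ± 68.5 to 343 ± 51.7 CPM.

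Mesenchymal genes went both ways: 7 of 35 rose and 12 fell, with 24 adjusted over the list alone (camera adjusted p = 0.35). SPARC, COL1A2 and COL3A1, which encode secreted matrix proteins, rose by 2.28 ± 0.48, 2.22 ± 0.55 and 2.15 ± 0.46. The matrix protease MMP3 fell by 2.63 ± 0.36, from 1.73 ± 0.163 to 0.271 ± 0.0689 CPM. The list had a median of -0.08 and a mean of 0.11. The collagen rises lay in 2 of the 3 knockdown libraries: COL1A2 held 24, 32 and 28 counts in the control libraries and 222, 31 and 160 in knockdown replicates 1 to 3. With knockdown replicate 2 alone, the log2 fold changes of SPARC, COL1A1, COL1A2 and COL3A1 were 0.93, 0.47, 0.04 and 0.70, and none passed.

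Markers of fibroblasts followed the same libraries. Of 10 markers, 5 could be tested and 4 of these rose, and 8 of the 10 were higher in knockdown replicates 1 and 3 than in each of the other 4 libraries. COL1A1, COL1A2 and COL3A1, among those that rose, and POSTN are also in the mesenchymal list, so they are not separate observations. Of the 8, DCN, PDGFRA, FAP and THY1 are outside it. The proteoglycan gene DCN held 9, 19 and 8 counts in the control libraries and 67, 22 and 74 in knockdown replicates 1 to 3. Leukocyte, hepatocyte and endothelial markers gave no rise. Of 15 leukocyte markers 1 was tested and did not pass, of 7 hepatocyte markers none could be tested, and of 9 endothelial markers 2 were tested and 1 fell. Markers of embryonic kidney and neural cells, which could come from cells used for virus packaging, gave 3 tested genes of 9, of which none rose and 1 fell.

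**Figure D3:**
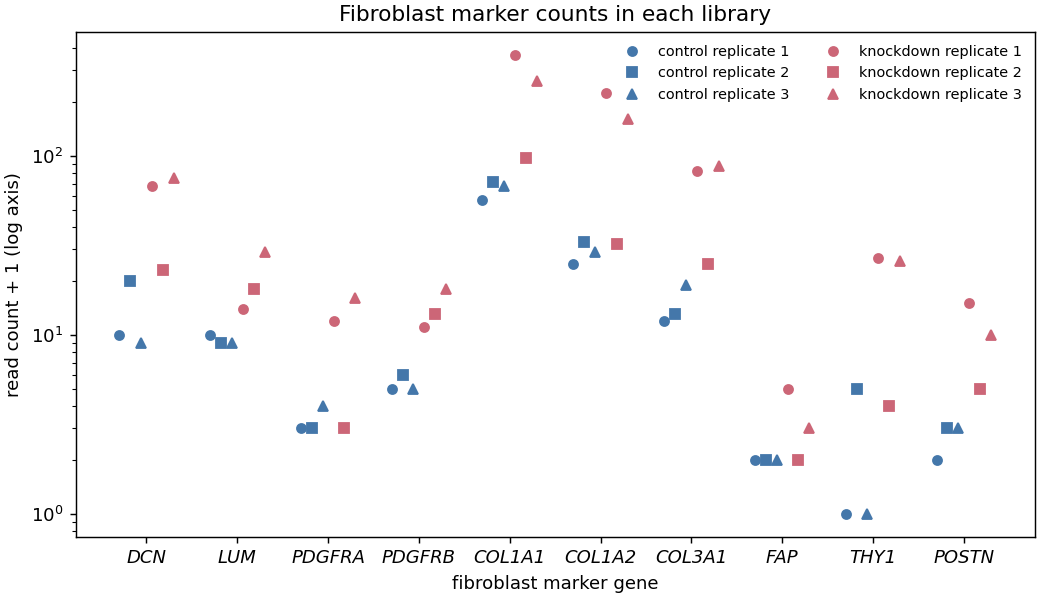
Read counts plus 1, on a log axis, of 10 fibroblast marker genes in each of the 6 libraries. Blue points are control and red points knockdown libraries, and the marker shape gives the replicate. COL1A2 stands at 222 and 160 counts in knockdown replicates 1 and 3, against 31 in knockdown replicate 2.

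Interferon-stimulated genes gave 6 rises and 3 falls among 34 tested, with 9 adjusted over the list alone (camera adjusted p = 0.518). GBP2 (2.60 ± 0.48), IFI44 (2.20 ± 0.51) and IFIT1 (1.38 ± 0.21) rose and GBP3 fell by 0.81 ± 0.12. GBP2 and IFI44 were near 0.357 and 0.179 CPM in the control libraries. Among 19 interferon receptors, JAK, STAT and regulatory factors, IRF1, a transcriptional activator of CD274, fell by 0.56 ± 0.12 and SOCS3 by 0.47 ± 0.13, with 2 adjusted over the list alone (camera adjusted p = 0.688). In antigen presentation, PSMB10 fell by 0.66 ± 0.18 among 9 genes tested, with 2 adjusted over the list alone (camera adjusted p = 0.185). Of 18 genes of RNA sensing and RNA interference, AGO2 rose by 0.68 ± 0.17, with 1 adjusted over the list alone (camera adjusted p = 0.871).

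Several stress response genes fell, though none of their 3 lists passed by camera with its preset correlation. HMOX1, the inducible heme oxygenase, fell from 393 ± 47.6 to 137 ± 16.2 CPM. With it OSGIN1 (-1.26 ± 0.18), FTL (-0.55 ± 0.14) and SQSTM1 (-0.48 ± 0.11) fell, among 5 falls and no rise in 27 NRF2 and glutathione genes, with 5 adjusted over the list alone (camera adjusted p = 0.0516; 0.0321 with voom weights and 0.511 with an estimated correlation). Of 21 endoplasmic reticulum chaperone genes, 4 fell and none rose, with 5 adjusted over the list alone (camera adjusted p = 0.0514; 0.511 with an estimated correlation). That list passed by fry (adjusted p = 0.0299), with voom weights (camera adjusted p = 0.03) and without GC content and length trends (camera adjusted p = 0.0127). DNAJB9, SDF2L1, HERPUD1 and SYVN1 fell by 0.71 ± 0.15, 0.70 ± 0.22, 0.67 ± 0.11 and 0.42 ± 0.12, and edgeR lost the call of SYVN1 in 5 of the 6 fits leaving out a library. Of 22 immediate early and heat shock genes, 4 fell and 1 rose, with 5 adjusted over the list alone (camera adjusted p = 0.0895; 0.0438 without knockdown replicate 3 and 0.59 with an estimated correlation). KLF4 (-1.60 ± 0.14), JUN (-0.71 ± 0.10) and DUSP1 (-0.46 ± 0.11) fell, and EGR1 rose by 0.71 ± 0.12.

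YAP and TAZ targets fell in 9 of 22 cases and rose in 2, with 13 adjusted over the list alone (camera adjusted p = 0.0514; 0.511 with an estimated correlation). The list passed with voom weights (camera adjusted p = 0.025), without the low-count filter (0.0114), without GC content and length trends (0.00936), and without control replicate 1 or 3 or knockdown replicate 1 or 2 (0.0358, 0.0172, 0.0265 and 0.016). FJX1 (-1.39 ± 0.14) and NUAK2 (-0.82 ± 0.15) fell, and AMOTL1 (1.01 ± 0.16) and FSTL1 (1.00 ± 0.13) rose. Transcripts raised by ERK gave 5 rises and 3 falls among 18, with 10 adjusted over the list alone (camera adjusted p = 0.11; 0.511 with an estimated correlation). The ERK list passed upward by fry (adjusted p = 0.0138). The ERK feedback gene SPRY2 rose by 0.76 ± 0.10, while FOSL1 (-0.95 ± 0.15) and HBEGF (-0.74 ± 0.21) fell, the call of HBEGF being lost in 4 of the 6 edgeR fits leaving out a library. Glycolysis and hypoxia genes rose in 9 of 34 cases and fell in 3, with 15 adjusted over the list alone (camera adjusted p = 0.315). MXI1, an antagonist of MYC (1.25 ± 0.16), PDK1 (0.75 ± 0.15) and SLC2A3 (0.96 ± 0.30) rose and the peptide gene ADM fell by 1.48 ± 0.19. SLC2A3 was at 0.975 CPM in the control libraries, and edgeR lost its call whenever any single library was left out.

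Among 25 p53 targets, 3 rose and 5 fell, with 9 adjusted over the list alone (camera adjusted p = 0.189; 0.511 with an estimated correlation). The p53 list passed downward by fry (adjusted p = 0.00887). TP53INP1 rose by 1.55 ± 0.21, and GADD45A, PLK2 (-0.94 ± 0.12) and SESN2 (-0.76 ± 0.11) fell. Of 30 apoptosis genes, 3 rose and 5 fell, with 8 adjusted over the list alone (camera adjusted p = 0.0879; 0.511 with an estimated correlation). That list passed downward by fry (adjusted p = 0.00142) and without the low-count filter (camera adjusted p = 0.0274). BMF rose from 1.90 ± 0.237 to 7.56 ± 1.95 CPM and CASP6 by 0.49 ± 0.11 on the log2 scale. The survival factors BIRC3 (-0.59 ± 0.10) and BCL2L1 (-0.50 ± 0.10) fell. Among 9 replication-dependent histone genes, HIST1H2BJ (-1.43 ± 0.28) and HIST1H2BK (-0.61 ± 0.13) fell, with 3 adjusted over the list alone (camera adjusted p = 0.11). The call of HIST1H2BK ended when trends on GC content and length were removed.

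In all, 6 of 33 lists moved by camera with its preset correlation, all of them downward: NF-kB cytokines, ribosome biogenesis, cholesterol synthesis, G1/S, ATF4 and the nuclear respiratory chain. None of the 33 passed with an estimated correlation, where 1 list, NF-kB cytokines, had an unadjusted p under 0.05 (p = 0.0386). By fry, which asks whether the members of a list move one way on balance, 11 lists passed. It does not compare them with other genes. Among the 11 were NF-kB cytokines (fry adjusted p = 0.00887), ATF4 (0.0168), cholesterol synthesis (0.0209), ribosome biogenesis (0.0379) and G1/S (0.0399). The nuclear respiratory chain did not pass (fry adjusted p = 0.534).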

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

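The tests of knockdown replicate 2, of library size and of the CD274 counts below were chosen after the values had been seen, as were the fits with knockdown replicate 2 alone and with GC content and length trends removed. The bounds for the GC tests and for the second fibroblast list were set before their results were seen. How a spread is read in the GC tests was changed after the results were seen: here a value must clear its bound and, with its standard error, lie outside the range that bias would give. Under the first reading the value with its standard error had to clear the bound, and the verdict on CD274 would be open. The verdict on G1/S would be open under the first reading too. Its value meets the reading used here, but the verdict is left open because its standard error is too small.

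Among 39 marker genes of other cell types too weakly counted for the test of all genes, 4 passed an exact test for more counts after knockdown than in the controls, each a fibroblast marker. Over the 3 libraries of each group, THY1 held 54 counts against 4 in the controls (exact binomial test, adjusted p = 5.24e-11), PDGFRB 39 against 13 (exact binomial adjusted p = 0.00247), PDGFRA 28 against 7 (exact binomial adjusted p = 0.00247) and POSTN 27 against 5 (exact binomial adjusted p = 0.00105). These tests cover counting error only.

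Most of the fibroblast transcripts were concentrated in knockdown replicates 1 and 3. LUM (13, 17 and 28 counts in knockdown replicates 1 to 3) and PDGFRB (10, 12 and 17) were exceptions, and FAP held at most 4 counts in any library. Library size does not account for the fibroblast transcripts, since the highest total was 1.12 times the lowest. An equal rise in every knockdown library does not account for them either: over the 10 markers, the ratio of CPM in knockdown replicate 2 to the mean of replicates 1 and 3 had a median of 0.303, with single markers between 0.115 and 0.859. The same ratio for the controls was 0.181, so a smaller rise in replicate 2 stays open. RNA of fibroblast-like cells in these 2 libraries is a candidate explanation, as a second fibroblast list of 54 genes had 45.8% of its 24 detected members, 11 genes, above all 4 other libraries, while none of 10000 expression-matched random lists reached that share and their median was 8.3%. Of those 24 genes, 4 are also in the mesenchymal list, and of the 20 outside it 7 were above all 4 other libraries. No margin was required, so the 11 differ in how far they follow the pattern. In knockdown replicates 1 to 3, IGFBP5 held 79, 11 and 57 counts, but CCDC80 held 71, 61 and 61. Abundant members such as COL12A1 (81.2 CPM) and FBLN1 (137 CPM) are expressed by the control cells and did not follow the pattern. A mesenchymal shift of the T24 cells themselves in these 2 libraries therefore stays open and was not tested.

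The falls of the gene lists were weighed against bias, because log2 fold changes ran with GC content (rank correlation across genes -0.26) and exonic length (0.25), and genes are not independent replicates. After per-library trends on both were removed, the median of the NF-kB list was -0.54 with a resampled standard error of 0.18 (-0.59 before, camera adjusted p = 2.26e-08). That of ribosome biogenesis was -0.40 ± 0.04 (-0.50 before, camera adjusted p = 2.26e-08). Cholesterol synthesis was at -0.30 ± 0.05 (-0.37 before, camera adjusted p = 4.57e-05). Each cleared its bound (-0.3, -0.25 and -0.2) by more than this standard error, which argues against these trends as the whole cause. The G1/S list was at -0.12 with a resampled standard error of 0.04 (-0.16 before, camera adjusted p = 0.00285). It lay outside the 0.05 around 0 that bias would give, but cleared its bound of -0.1 by less than this standard error. Resampling treats the members of a list as independent and leaves out the spread between libraries. Members of the G1/S list had an estimated correlation of 0.127, so its standard error is too small and the test does not settle its fall. For the NF-kB, ribosome biogenesis and cholesterol lists it was 0.193, 0.398 and 0.165, so their standard errors are too small as well. Their margins are therefore less certain than stated, most of all for NF-kB cytokines, with the largest standard error. The ATF4 list was at -0.12 with a resampled standard error of 0.07 (-0.16 before, camera adjusted p = 0.0213). It cannot be told apart from such a trend, because its spread reaches that range. An effect of the knockdown stays among the open explanations. None of these lists passed with an estimated correlation, while all of them passed by fry, which does not compare a list with other genes.

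The rise of CD274 was weighed against the same causes. Without GC content and length trends its log2 fold change was 1.201 ± 0.388 (edgeR adjusted p = 0.0445), above the 0.4 that this bias would leave by more than its standard error, which argues against it as the whole cause. It cleared the bound of 0.9 by less than its standard error. Knockdown replicate 2, which had few fibroblast transcripts, held 0.928 of the CD274 CPM of replicates 1 and 3, but with 19 counts the exact 95% interval runs from 0.508 to 1.64. RNA of fibroblast-like cells therefore cannot be told apart from a rise in the T24 cells at this depth, and an effect of the knockdown stays open.

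The count of 2402 changed genes was set against the other ways of splitting the 6 libraries into 3 and 3. Of the 10 splits, 1 gave as many, the real one, and the highest of the others gave 0. With 10 splits the share cannot fall under 0.1, so the design does not allow chance to be excluded at 0.05 this way.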

How the results depend on the processing

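The fits with GC content and length trends removed and with knockdown replicate 2 alone were chosen after the result was seen; the other alternatives were set before the data were examined.

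The fall of MTHFD2 held in every alternative, between -2.62 and -2.39 with any library left out. CD274 lost its call in most: its log2 fold change was 1.281 by DESeq2 (adjusted p = 0.127), 1.271 in edgeR without the low-count filter (adjusted p = 0.0569) and 1.197 with knockdown replicate 2 alone (edgeR adjusted p = 0.164). It ran from 0.996 without control replicate 1 to 1.474 without control replicate 2, and under the stricter filter it was not tested.

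With a library left out, the number of changed genes ran from 986 without control replicate 3 to 2645 without knockdown replicate 3. It was 1003 without control replicate 1 and 1469 without knockdown replicate 2. In the same fits, higher genes ran from 600 without control replicate 1 to 1468 without knockdown replicate 3. Lower genes ran from 368 without control replicate 3 to 1213 without knockdown replicate 1. Without the low-count filter 3028 genes changed, and without GC content and length trends 3348. Knockdown replicate 2 alone gave 4432 genes, 2212 higher, 2220 lower and 953 at least 2-fold. At an adjusted p under 0.01 there were 749, 472 higher, 277 lower and 297 at least 2-fold. The stricter filter left 308 genes at least 2-fold, and without GC content and length trends 1595 genes were lower. No named gene reversed.

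With the replicate block, which treats equal replicate numbers as paired, 5062 genes changed, 2566 higher and 2496 lower. Deviations of equal numbers correlated by -0.02, 0.297 and 0.353, and those of unequal numbers by -0.405 to 0.165, so replicates 2 and 3 give partial support for pairing and replicate 1 none.

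Of the gene lists, 0 moved by camera with an estimated correlation, 14 without the low-count filter, 11 by fry, 10 with voom weights, 10 without GC content and length trends and 12 with knockdown replicate 2 alone. Between 6 (without control replicate 3) and 12 (without control replicate 1, and likewise without knockdown replicate 3) moved with a library left out. Of 121 named genes called, 73 kept the call in every alternative fit that tested them, 71 of these also at an adjusted p under 0.01, and 9 of the 121 were not tested under the stricter filter. Apart from CD274, 44 named genes lost their call in at least 1 fit leaving out a library, and the text above does not mark each of them.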

Other observations

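The word and window tests below were set before their results were seen. The gene families were formed by a fixed rule after the other results, the fit of words one after another was added after the single words were seen, and metallothionein genes were picked after their values were seen.

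Of 4 metallothionein genes tested, MT2A fell from 2794 to 1529 CPM, a log2 fold change of -0.87 ± 0.15 (edgeR adjusted p = 0.00312), and MT1X fell by 0.84 ± 0.17 (edgeR adjusted p = 0.00698), besides MT1E. MT1F did not pass (edgeR adjusted p = 0.13). The genes were not tested as a group, and their reads are hard to tell apart, so the 3 falls are not separate findings.

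Genes were grouped into 151 families by the letters that open their symbols, with at least 10 tested members each, and falls and rises were compared with all other genes by Fisher's exact test over 302 tests. Of 16 KRT genes, pseudogenes included, 8 fell and 0 rose (exact adjusted p = 0.00139 for falls), with KRT18, the partner of KRT8, going from 1192 to 642 CPM. As 3 of the 8 are pseudogenes of KRT8 or KRT18 that may share reads with them, the members cannot be counted as independent and this p may be too low. Of 17 SNHG genes, noncoding hosts of small nucleolar RNAs, 7 fell and 0 rose (exact adjusted p = 0.0135). Of 24 GPR genes, orphan and other G protein-coupled receptors, 10 rose and 1 fell (exact adjusted p = 0.0052). Zinc finger genes of the ZNF family passed the threshold less often than other genes: of 428, 24 rose (exact adjusted p = 0.0325) and 13 fell (exact adjusted p = 0.00139), where 10.4% and 8.2% of all grouped genes did. Families were not matched for expression, on which the chance of a call depends. Genes of the RPL family, most of them pseudogenes, rose in 1 of 136 cases (exact adjusted p = 0.00139). After GC content and length trends were removed, the KRT, SNHG, GPR and both ZNF tests still passed, with exact adjusted p-values of 0.013, 0.014, 0.00635 and 0.000304 for each ZNF test. The RPL test for rises did not (9 of 136, exact adjusted p = 0.222). Only then did 9 other tests pass, the lowest p being for DDX helicases, of which 17 of 35 fell (exact adjusted p = 6.2e-05; 9 fell before, exact adjusted p = 0.0532).

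A hairpin can lower other transcripts through a short seed match in their 3′ UTRs. As a test of this hypothesis, all 15656 words of 7 bases found in at least 100 of 11451 3′ UTRs were compared with the corrected fold change, allowing for UTR length, base composition and expression. Against a lowest z of -4.88 in 100 permutations, 16 words passed, and 6 of them are in the MTHFD2 transcript, which holds 22.2% of all words. The lowest z of a word in that transcript was -5.65. Fitted one after another, 3 words passed: CCGAGGC, which the MTHFD2 transcript lacks, ACATACA and GGAGTGC, which it holds, with shifts of -0.09, -0.07 and -0.07 on the log2 scale. A seed effect may be among these but cannot be told apart from other features of the UTRs, since words absent from MTHFD2 passed as well and the hairpin sequence is not given in the sources used here.

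Drift in copy number between the 2 cultures was the other hypothesis tested. Over windows of 50 neighbouring tested genes on the autosomes, the highest absolute median log2 fold change, with GC content and length trends removed, was 0.246, reached on chromosome 12 from SPSB2 to CDKN1B and on chromosome 9 from GBA2 to ZNF658, and shuffled gene orders reached 0.287. Before that correction a window on chromosome 1 from 629640 to 3652761 had a median of -0.306, which became -0.178. No window of 11309 passed after it, while a simulated shift of 0.5 over 100 genes was found. This argues against a copy-number difference of that size and length as a source of the changed genes.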
